A study of Arabidopsis thaliana with 14 samples.

How the data were processed

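Seeds of Arabidopsis thaliana Ws-0 plants 38 to 46 days old, grown under continuous light, were fixed in ethanol and acetic acid and embedded in paraffin, and compartments were captured from sections by laser microdissection, per the labels' protocols. RNA was isolated with a column kit including a DNase step, and 2 to 5 ng (micropylar endosperm) or 5 to 6 ng (other groups) was amplified and labelled with biotin before hybridisation to ATH1 arrays, per the labels' protocols. The deposited values are signal intensities on a linear scale from GCOS, per the submitters' processing notes; its version is not given in the sources used here. The intensities were already scaled by the authors: on each of the 14 arrays the 2% trimmed mean is 500, as found from the values. Values ran from 0.06 to 402000. No detection calls or probe-level files were used here. Values of hybridisation controls spiked in at a fixed amount differed between arrays after this scaling, from 81931 (micropylar endosperm replicate 3) to 344582 (general seed coat replicate 1) for the Cre control.

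The comparisons, their tests, the fixed gene lists, the rule for named genes and the alternatives were fixed before the data were examined. What was added later is named below. Samples were grouped by the labels' titles, sources and descriptions into 7 groups of 2 biological replicates. The labels number the micropylar endosperm replicates 1 and 3 and the others 1 and 2.

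Of 22810 probe sets, 64 controls were left out. A probe set was tested if it lay above the array's own median on both arrays of at least 1 group, which kept 14765 of 22746 (64.91%). The values as deposited were changed to log2(value + 32) and fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, over all 14 arrays in a single fit with 7 residual degrees of freedom (median 16.99 after moderation). A fold change on this scale understates the change of dim probe sets. P-values were adjusted by Benjamini-Hochberg over all probe sets tested in each contrast, and a call needed an adjusted p under 0.05 and a log2 difference of at least 1. A probe set counted as enriched in a compartment if it passed against each of the other 5, and the adjusted p given for an enriched gene is the largest of the 5. Contrasts compared the embryo proper, the mean of the 3 endosperm regions and the mean of the 2 seed coat regions, the subregions within the endosperm and within the seed coat, and whole seeds with the mean of the 6 compartments. Text levels are means and SDs of the deposited intensities.

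Gene names came from GEO's platform annotation, with symbols updated through the RefSeq TAIR10.1 gene table, used for names only. A single gene was named for 13513 probe sets, of which 13436 were found in that table and 77 were not. Several genes were named for 503 and none for 8794, and these were not given gene names. Genes named in the text are the 12 enriched genes of each compartment with the largest difference to the next-highest, the 10 higher and 10 lower genes of each region contrast with the largest difference (5 and 5 for whole seeds), and up to 4 members of each gene list with the largest differences past the threshold. Other list members and family members appear as values. This gave 191 genes in 249 gene and comparison pairs.

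The fixed lists held 318 genes in 21 lists, of which 48 had a probe set with a single gene and 36 were tested. Lists with at least 2 tested genes, 12 in number, were tested with camera in limma with a preset correlation of 0.01, with the brightest probe set per gene, in 13 contrasts (each compartment against the mean of the other 5, and the 7 region and subregion contrasts), and adjusted over the 156 tests. Of these, 66 were called, and 0 with an estimated correlation, where 50 had an unadjusted p under 0.05 and the lowest adjusted p was 0.126. A further 22 gene families were chosen after the annotation and the global counts had been seen, and the percentiles of levels relative to a neighbouring compartment and the splits of whole compartments were chosen after the results they measure.

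The tests were run on simulated data with the mean and fitted spread of each of the 14765 probe sets and 50 changed probe sets per size, drawn from the brighter ones. Of those changed by a log2 difference of 2, the embryo proper enrichment recovered 30% with 0 false calls and the region and subregion contrasts between 46% (micropylar against chalazal endosperm, 5 false calls) and 100% (endosperm against seed coat, 4 false calls), with at most 8 false calls (micropylar against peripheral endosperm). At a log2 difference of 3, the embryo proper enrichment recovered 90%. In the embryo proper contrast over 8071 genes, camera called 20 of 20 shifted lists of 4 genes and 0 of 20 unshifted ones with either correlation. The simulated genes varied independently, so this does not test camera on genes that vary together. The real lists held such genes, with an estimated correlation of 0.736 for sugar transport genes. Alternatives were quantile normalization, log2(value + 1), log2(value + 100), no filter, a filter at the 75th percentile, no intensity trend, the replicate number as a block, the mean over a gene's probe sets, fits without the whole seed or the micropylar arrays, and fits without each array in turn. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.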

Results

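The data are 14 Affymetrix ATH1 arrays of Arabidopsis thaliana seeds (accession Ws-0) at the bending-cotyledon stage, with a pair of biological replicates in each of 7 groups. Of these groups, 6 are compartments captured by laser microdissection from fixed and paraffin-embedded seeds: the embryo proper, the micropylar, peripheral and chalazal endosperm, the chalazal seed coat and the general seed coat. The remaining group consists of serial sections of whole seeds. Seeds came from plants 38 to 46 days old, with cotyledons 100 to 140 µm long. Each value is a probe set's linear signal intensity, scaled by the authors so that the trimmed mean of each array is 500. Array medians lay between 99.07 and 188.1. All levels below are the mean ± SD of the intensity with n = 2 arrays, which limits the precision. Of the 22810 probe sets, 14765 were bright enough to be tested, and 8175 of those carry the name of a single gene. The sampling addresses which transcripts mark each compartment, how the embryo, endosperm and seed coat differ, and how subregions of the endosperm and of the seed coat differ from each other. For the micropylar endosperm samples, a cell type field in the labels names the embryo proper, while their titles, sources and descriptions name the micropylar endosperm. They were grouped by the latter.

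Replicate arrays of a group correlated with r between 0.8672 (peripheral endosperm) and 0.9671 (embryo proper) across probe sets, which are not independent replicates. Arrays of different groups reached 0.4378 to 0.8834. The highest of these values joins peripheral endosperm replicate 2 and micropylar endosperm replicate 1, which were closer to each other than the peripheral endosperm replicates were. Mean profiles of the micropylar and peripheral endosperm correlated with r = 0.8801, while the chalazal endosperm reached 0.6013 with the micropylar and 0.6325 with the peripheral endosperm. The embryo proper and the chalazal seed coat were the most distant pair, with r = 0.457. Ratios of 3′ to 5′ control probe sets, a sign of RNA integrity, ran from 2.17 to 7.495 for GAPDH, with the highest on micropylar endosperm replicate 3, from 5.099 to 9.025 for ubiquitin, with the highest on embryo proper replicate 2, and from 0.4405 to 2.378 for actin, with the highest on embryo proper replicate 1.

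**Figure D1:**
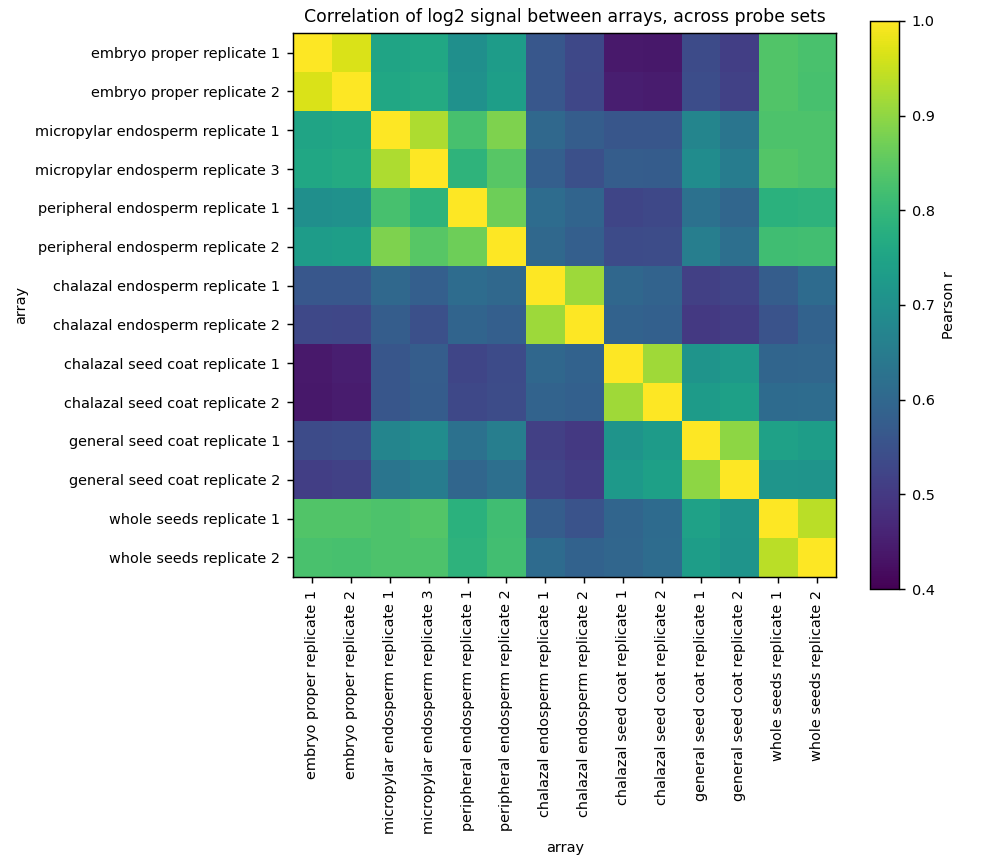
Pearson correlation of log2 signal across probe sets for each pair of the 14 arrays (both axes list the arrays by group and replicate, the colour gives r). Replicates lie between 0.8672 and 0.9671, and the lowest value between groups is 0.4378.

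Storage protein, photosynthesis and cell cycle genes were high in the embryo proper. YAB3, a YABBY transcription factor of abaxial cell identity, had a level of 2101 ± 37.7 in the embryo and 45.06 ± 9.5 in the general seed coat, the next-highest compartment. AT5G44310, a late embryogenesis abundant (LEA) gene, was at 13170 ± 195 in the embryo and 1130 ± 1170 in the micropylar endosperm. STOMAGEN, which encodes a secreted peptide that promotes stomatal development, stood at 978.5 ± 173 in the embryo and at 43.02 ± 35.4 in the general seed coat. AT5G01075, listed as TWS1, a peptide precursor needed for the embryonic cuticle, was at 3838 ± 406 in the embryo and 319.9 ± 417 in the micropylar endosperm. The largest gap to the next-highest compartment belonged to AT1G62500, at 7252 ± 750 against 146.2 ± 204 in the micropylar endosperm, a log2 difference of 6.12 ± 0.84 (SE) with an adjusted p of 7.22e-05.

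Against the mean of the other 5 compartments, 4 of 4 tested seed storage protein genes were higher in the embryo proper (camera adjusted p = 0.000835), with PAP85 at 1908 ± 22.3 there and 28.43 ± 31.3 in the chalazal seed coat. Photosynthesis genes followed, 4 of 4 higher (0.000297), such as PSAN at 12070 ± 867 and RCA, rubisco activase, at 3720 ± 413. So did 3 of 3 cell cycle genes (0.0181), with the Aurora kinases AUR1 at 1117 ± 21.3 and AUR2 at 1791 ± 499 and PRL, a subunit of the MCM replication helicase, at 1898 ± 22.6. AUR1 had higher means in the peripheral (1198 ± 56.8) and chalazal endosperm (1336 ± 486), while AUR2 and PRL had their highest means in the embryo. The oil body genes OLEO3 and AT3G01570 (2 of 2, adjusted p = 0.00767), the patterning genes YAB3 and PHV (2 of 2, 0.0179; PHV was at 551.6 ± 15.1 in the embryo and at 821.9 ± 49.1 in the peripheral endosperm) and 3 of 6 LEA genes (0.0311) were also higher. Both oil body genes had lower means in the embryo than in the peripheral endosperm. OLEO3 was at 35330 ± 953 against 37800 ± 382 and AT3G01570 at 3290 ± 477 against 5189 ± 1040. Lower in the embryo were the flavonoid genes BAN and DFR (2 of 2, 0.00676), 3 of 4 seed coat mucilage genes (0.015) and the sugar exporters SWEET11 and SAG29, also called SWEET15 (2 of 2, 0.0187, not called with log2(value + 1)). With an estimated correlation between genes the adjusted p was 0.126 for 7 of these lists, 0.342 for the LEA genes and 0.183 for the sugar transport genes. For every list in this text the count adjusted over the list alone is the same as the count over all genes tested unless both are given.

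In limma, 409 probe sets (2.77% of those tested, 183 with a single gene) were higher in the embryo proper than in each of the other 5 compartments, and for 139 of them the next-highest compartment was the micropylar endosperm. The count was 179 without embryo proper replicate 1, 185 without embryo proper replicate 2, 249 without micropylar endosperm replicate 1 and 205 with log2(value + 1).

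The micropylar endosperm shared storage, oil body and photosynthesis transcripts with the embryo and had a short list of transcripts of its own. AT1G09370 was at 3751 ± 135 there and at 130.1 ± 114 in the chalazal endosperm, the next-highest compartment, a log2 difference of 4.75 ± 0.57 (SE) with an adjusted p of 0.000211. AT1G04645 stood at 5737 ± 232 against 382.3 ± 77.1 in the peripheral endosperm. DI21, a drought-induced gene, reached 7423 ± 246 against 888.2 ± 66.6 in the embryo proper. AT2G22420 was at 2420 ± 149 in the micropylar endosperm and 231.1 ± 42.5 in the embryo proper.

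Of the lists, 3 of 4 storage protein genes (adjusted p = 0.000857), 2 of 2 oil body genes (0.00094) and 4 of 4 photosynthesis genes (0.000297) were higher in the micropylar endosperm than in the mean of the other compartments. OLEO3, an oleosin, was at 30190 ± 891 and LHCB4.1, a light-harvesting protein, at 9463 ± 2430. Mucilage genes were lower, 2 of 4 over all genes tested and 3 of 4 adjusted over the list alone (adjusted p = 0.0181, not called with log2(value + 1)). All 4 lists had an adjusted p of 0.126 with an estimated correlation. These storage levels differed in spread between arrays: the geometric mean of the storage genes was 3916 ± 1810 in the micropylar endosperm and 6415 ± 89.9 in the embryo. In a test chosen after these results were seen, among 241 transcripts that were higher in the embryo than in the 4 compartments other than the micropylar endosperm and brighter than 2000 in the embryo, the 5th percentile of the level relative to the embryo was 8.12% on micropylar replicate 3 and 1.17% on micropylar replicate 1. Among 224 bright general seed coat transcripts chosen in the same way it was 2.05% and 0.429%.

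The 5 contrasts in limma left 51 probe sets (31 with a single gene) enriched in the micropylar endosperm, with the peripheral endosperm next-highest for 19. This count was 31 without embryo proper replicate 1, 29 without embryo proper replicate 2, 21 without micropylar replicate 1, 20 without micropylar replicate 3, 23 without peripheral replicate 1, 86 without peripheral replicate 2, 20 with log2(value + 1) and 111 with log2(value + 100).

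The sugar exporter SWEET11 and a cellulase stood out in the peripheral endosperm. SWEET11 was at 11560 ± 1360 there, at 4182 ± 1970 in the micropylar endosperm and at 219.6 ± 87.4 in the embryo proper. SAG29 was at 3777 ± 1450 in the peripheral endosperm, at 4768 ± 1210 in the general seed coat and at 27.05 ± 10.3 in the embryo. GH9C1, a family 9 glycosyl hydrolase of the cellulase type, reached 13550 ± 1800 against 2783 ± 566 in the micropylar endosperm, a log2 difference of 2.28 ± 0.40 (SE) with an adjusted p of 0.00364. AT3G62820 had the largest gap, 2666 ± 541 against 104.8 ± 7.15 in the micropylar endosperm, with a log2 difference of 4.29 and an adjusted p of 0.000637.

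Sugar transport genes (2 of 2, adjusted p = 0.000627), oil body genes (2 of 2, 0.000835) and photosynthesis genes (4 of 4, 0.000297) were higher in the peripheral endosperm than in the mean of the other compartments, each with an adjusted p of 0.126 with an estimated correlation. Storage genes were not called (1 of 4 higher, adjusted p = 0.146). The higher one, AT4G36700, was at 35480 ± 2600 in the peripheral endosperm and 18830 ± 710 in the embryo. The others had lower means than in the embryo, such as AT2G28490 at 345.4 ± 345 against 2582 ± 97.8. PSAE-1, a photosystem I subunit, was at 11560 ± 750 and OLEO3 at 37800 ± 382. In limma 81 probe sets (35 with a single gene) were enriched, and the micropylar endosperm was next-highest for 41. The count was 53 without embryo proper replicate 1, 18 without micropylar replicate 3, 24 without peripheral replicate 1, 152 without peripheral replicate 2, 33 with log2(value + 1), 124 with log2(value + 100) and 313 without both micropylar arrays.

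The chalazal endosperm had the most enriched transcripts of the 6 compartments and low levels of the oil body and photosynthesis genes that the other endosperm regions shared with the embryo, and of the storage genes that the micropylar region shared with it. AT1G14580 was at 13700 ± 1800 there and at 800.4 ± 36.3 in the micropylar endosperm, the next-highest. CYP71B25, a cytochrome P450, reached 4856 ± 1070 against 351.4 ± 128 in the chalazal seed coat. AT3G60700 was at 23470 ± 2680 against 1959 ± 128 in the chalazal seed coat, and AT3G11740 at 7415 ± 805 against 435.6 ± 106. AT2G44250 had the largest gap, 3743 ± 1580 against 106.9 ± 122 in the chalazal seed coat, a log2 difference of 5.05 ± 0.71 (SE) with an adjusted p of 3.74e-05.

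Lower in the chalazal endosperm than in the mean of the other compartments were 4 of 4 storage genes (adjusted p = 0.00354), 2 of 2 oil body genes (0.00556), 4 of 4 photosynthesis genes (0.00144), 2 of 2 flavonoid genes (0.0129), 3 of 4 mucilage genes (0.00709) and 2 of 2 sugar transport genes (0.0105). AT2G28490, a vicilin-like storage protein gene, was at 4.167 ± 0.861, PSAN at 68.5 ± 82.2 and SWEET11 at 30.19 ± 37. The adjusted p with an estimated correlation was 0.159 for storage, 0.161 for photosynthesis and sugar transport and 0.126 for the others. Of the cell cycle genes 1 of 3 was higher, with a median below 0, a mean above 0 and no call (adjusted p = 0.895), and AUR1 stood at 1336 ± 486.

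A total of 602 probe sets (4.08% of those tested, 357 with a single gene) were enriched, and for 294 the next-highest compartment was the chalazal seed coat. In the same kind of test on the chalazal seed coat arrays, also chosen later, the 5th percentile of the level relative to the chalazal endosperm was 6.89% over 373 bright chalazal endosperm transcripts chosen without regard to the chalazal seed coat, against 0.327% on the general seed coat arrays. The choice required lower levels in the general seed coat. With log2(value + 1) the count of enriched probe sets was 363.

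Flavonoid and mucilage genes and a sugar exporter were high in the chalazal seed coat, where the vascular supply of the seed ends. The exporter, SWEET10, was at 16150 ± 305 there and at 58.89 ± 65.6 in the chalazal endosperm, the next-highest, a log2 difference of 7.69 ± 0.54 (SE) with an adjusted p of 1.58e-07. AT1G43910 was at 13620 ± 1780 against 72.5 ± 40.8 in the peripheral endosperm. AT3G50990, listed as the mucilage peroxidase PER36, was at 4962 ± 742 against 144 ± 37.7 in the general seed coat. The other mucilage genes tested had higher means in the general seed coat, such as ARA12 at 32820 ± 2320 against 18260 ± 3520 in the chalazal seed coat. AT5G24580 reached 14310 ± 3630 and AT3G14780 reached 8457 ± 1460, each at or below 144.7 ± 46 in the other compartments.

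Flavonoid genes (2 of 2, adjusted p = 0.00222) and mucilage genes (4 of 4, 0.000377) were higher in the chalazal seed coat than in the mean of the other compartments. BAN, the anthocyanidin reductase of proanthocyanidin synthesis, was at 2438 ± 254 and at 651.7 ± 161 in the general seed coat, and DFR, dihydroflavonol reductase, at 6577 ± 181 and 2559 ± 478. Lower were storage genes (4 of 4, 0.000835), oil body genes (2 of 2, 0.000568), photosynthesis genes (3 of 4, 0.000297) and cell cycle genes (3 of 3, 0.0175), with LHCB4.1 at 501 ± 60 and PRL at 212.8 ± 110. All 6 lists had an adjusted p of 0.126 with an estimated correlation. Enrichment in the chalazal seed coat was called for 412 probe sets (211 with a single gene), with the general seed coat next-highest for 162, and for 233 with log2(value + 1).

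Mucilage and flavonoid genes were also high in the general seed coat. AT1G62070 was at 76690 ± 19900 against 2943 ± 1730 in the chalazal seed coat, although its mean in the micropylar endosperm was 4296 ± 5330. ATPMEPCRD, related to pectin methylesterases, was at 6692 ± 1110 against 364.5 ± 313 in the micropylar endosperm. AT5G15740 stood at 20520 ± 3270 against 1230 ± 752 in the chalazal seed coat. AT1G66460 had the largest gap, 8148 ± 2490 against 227.3 ± 85 in the chalazal seed coat, a log2 difference of 4.99 ± 0.84 (SE) with an adjusted p of 0.000499.

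Of the mucilage genes, 3 of 4 were higher than in the mean of the other compartments (adjusted p = 0.000568): AT2G22900, listed as MUCI10, at 11840 ± 2050, AT3G10320, listed as MUCI21, at 1280 ± 353, and ARA12, the subtilase SBT1.7, at 32820 ± 2320. Flavonoid genes were higher too (2 of 2, 0.0134), and cell cycle genes lower (3 of 3, 0.0129), with AUR2 at 172.3 ± 57.5. All 3 lists had an adjusted p of 0.126 with an estimated correlation. Maturation regulators (EEL and BZIP53), fatty acid synthesis genes (FaTA and FATB) and the genes listed under embryo-surrounding endosperm (AT1G50650, listed as KRS, and AT5G01075) were not called in camera in any of the 6 compartments. Their lowest adjusted p was 0.0635 (maturation regulators, higher in the peripheral endosperm, unadjusted p = 0.0281), 0.136 (fatty acid synthesis, higher in the peripheral endosperm) and 0.0725 (embryo-surrounding endosperm list, lower in the chalazal seed coat, unadjusted p = 0.0335). The last list joined genes of different compartments. Against the mean of the others, AT5G01075 was higher in the embryo proper (log2 difference 5.57). AT1G50650 was higher in the peripheral endosperm (5.36) and at -1.02 in the embryo proper. In limma 369 probe sets (189 with a single gene) were enriched in the general seed coat, with the chalazal seed coat next-highest for 215. This count was 221 without chalazal seed coat replicate 1, 221 without general seed coat replicate 2 and 183 with log2(value + 1).

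**Figure D2:**
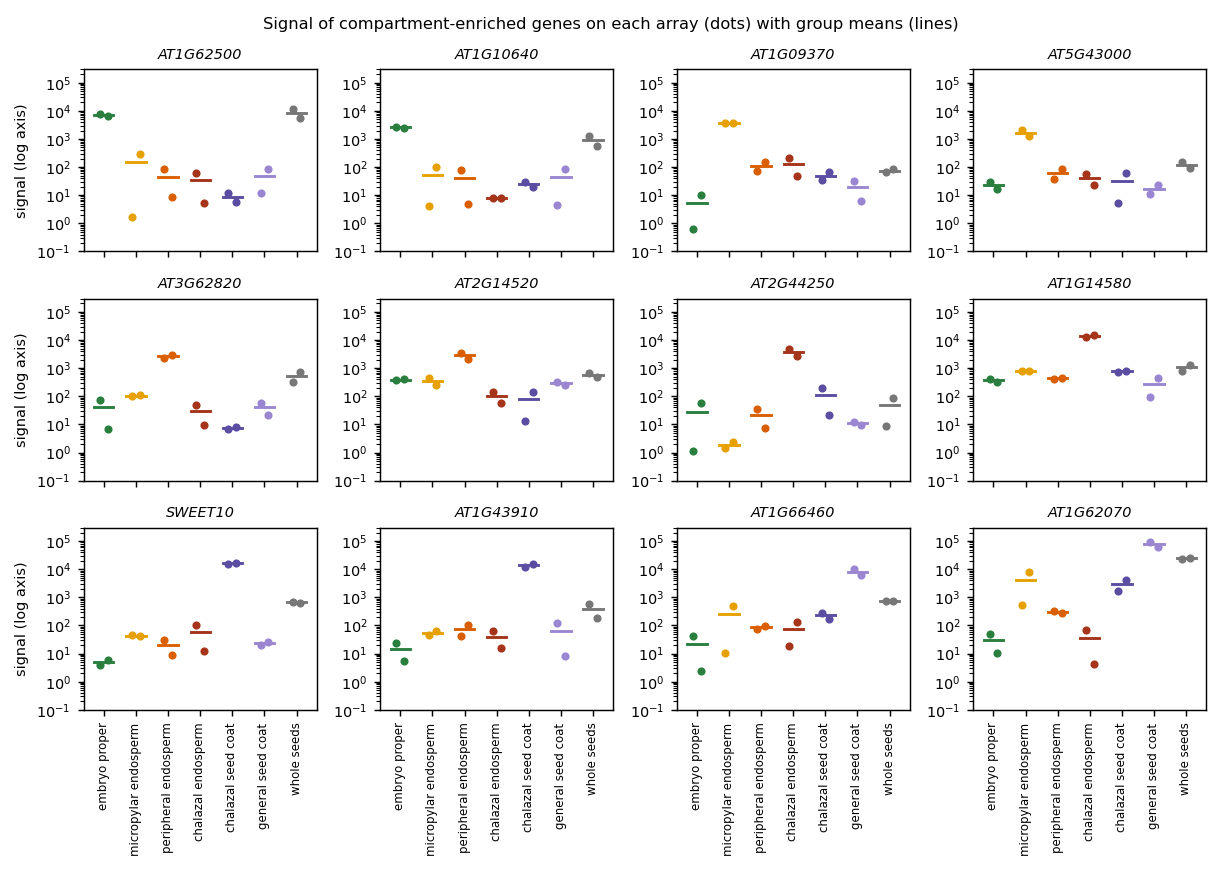
Signal on a log axis of the 2 genes with the largest gap to the next-highest compartment for each of the 6 compartments (dots are the arrays of each group, lines the group means). AT1G62500 stands at 7252 in the embryo proper and SWEET10 at 16150 in the chalazal seed coat.

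**Figure D3:**
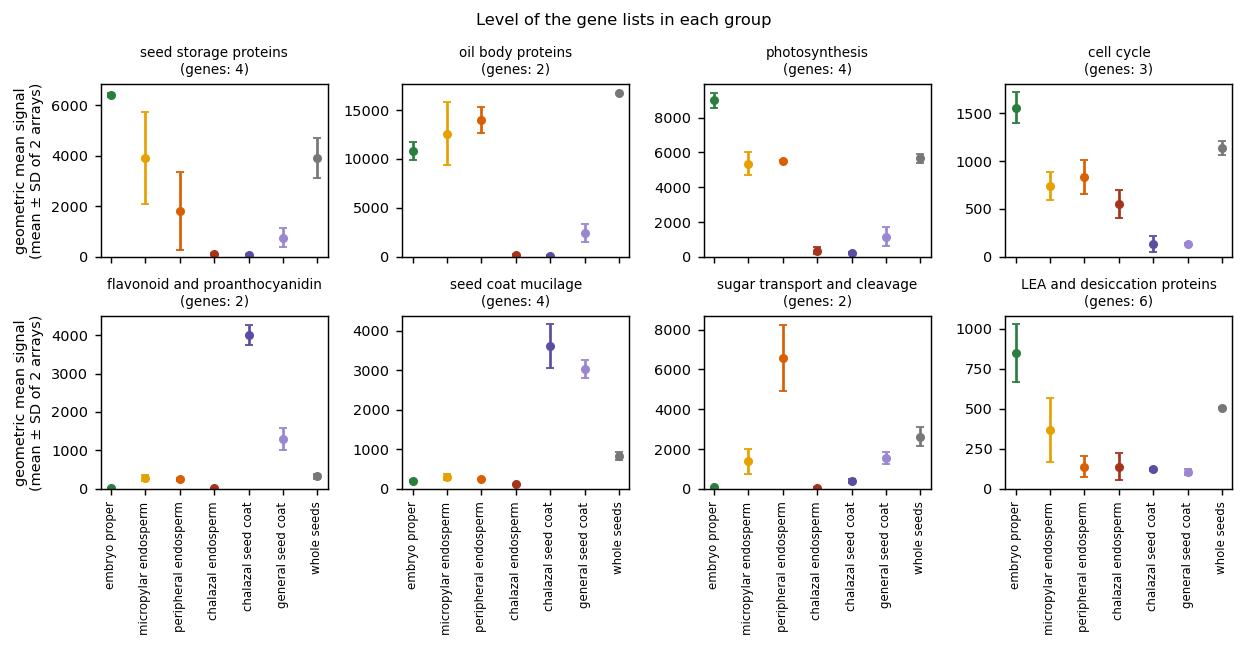
Geometric mean signal of 8 gene lists in each group (dots, mean of 2 arrays; bars, ± SD; linear axis from 0). Storage genes stand at 6415 in the embryo proper and 80.57 in the chalazal seed coat, and flavonoid genes reach 4007 in the chalazal seed coat.

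Compared with the mean of the 3 endosperm regions, the embryo proper was higher in storage, LEA and nuclear-encoded photosynthesis transcripts and lower in sugar transport and flavonoid transcripts. YAB3 was higher by a log2 difference of 5.56 and AT5G44310 by 5.81. PDF2.1, a plant defensin, was at 157.3 ± 82.6 in the embryo and 19010 ± 551 in the micropylar endosperm, a log2 difference of -5.76 ± 0.31 (SE) with an adjusted p of 2.09e-09. UGT84B1, a glucosyltransferase, was at 32.76 ± 33.3 in the embryo and 23840 ± 2800 in the chalazal endosperm. AT5G07260 was at 3.863 ± 2.9 in the embryo and between 4380 ± 238 and 12280 ± 1830 in the endosperm regions. Storage genes were higher (4 of 4, adjusted p = 0.00211, and 0.147 with an estimated correlation), as were photosynthesis genes (4 of 4, 0.00126, and an adjusted p of 0.161 with an estimated correlation) and 3 of 6 LEA genes (0.022, and an adjusted p of 0.306 with an estimated correlation). Oil body genes (2 of 2, 0.0372, not called with log2(value + 100)) and patterning genes (1 of 2, 0.0257, not called with log2(value + 1)) were higher, with an adjusted p of 0.161 and 0.126 with an estimated correlation. The oil body call came from the chalazal endosperm, with a geometric mean of 212.5 ± 48.7. The embryo, at 10800 ± 924, was not above the micropylar (12590 ± 3190) or peripheral endosperm (13980 ± 1340). The storage gene AT4G36700 was also lower in the embryo (18830 ± 710) than in the micropylar (24510 ± 2890) and peripheral endosperm (35480 ± 2600). LHCB4.1 (12190 ± 527 against 11860 ± 119) and PSAE-1 (12010 ± 318 against 11560 ± 750) were near their peripheral endosperm levels. The other storage and photosynthesis genes had higher means in the embryo than in each endosperm region. Lower were sugar transport genes (2 of 2, 0.00874, not called with log2(value + 1)) and flavonoid genes (2 of 2, 0.036, not called with log2(value + 100)), with an adjusted p of 0.159 and 0.14 with an estimated correlation. The chalazal endosperm did not share this. Its geometric mean was 41.35 ± 51.3 for sugar transport genes (87.79 ± 10.7 in the embryo) and 14.9 ± 11.2 for flavonoid genes (12.52 ± 2.38). Of the mucilage genes 1 of 4 was lower, and their median was above 0 while their mean was below 0 (adjusted p = 0.899). In all, 3766 probe sets differed, 2156 higher and 1610 lower in the embryo. The count was 1946 without embryo proper replicate 1 and 1910 without embryo proper replicate 2.

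Against the seed coat, taken as the mean of its 2 regions, embryo storage, photosynthesis and division transcripts were higher and flavonoid and mucilage transcripts lower. AT5G44310 differed by 7.28 and AtLEA4-1, at 2490 ± 207 in the embryo, by 5.61 on the log2 scale, while LEA18 was lower (-2.10) and the LEA genes were not called as a list (4 of 6 higher, 1 lower, adjusted p = 0.0635). FaTA, an acyl-ACP thioesterase of fatty acid synthesis, was at 5553 ± 322 in the embryo, 651.3 ± 114 in the chalazal and 1288 ± 202 in the general seed coat. FATB, the other such gene tested, was lower in the embryo (-1.17, adjusted p = 0.00158), and the list was not called (adjusted p = 0.643). GILT was at 11.19 ± 9.08 in the embryo and 59420 ± 364 in the general seed coat, a log2 difference of -9.15 ± 0.56 (SE) with an adjusted p of 2.48e-09. EXLA1, an expansin-like gene, was at 85.1 ± 10.4 in the embryo and 30500 ± 3290 in the general seed coat. Photosynthesis genes (4 of 4, adjusted p = 0.000297), storage genes (4 of 4, 0.000897), oil body genes (2 of 2, 0.00499), patterning genes (2 of 2, 0.022) and cell cycle genes (3 of 3, 0.00643) were higher. Mucilage genes (4 of 4, 0.000568) and flavonoid genes (2 of 2, 0.0049) were lower, DFR by a log2 difference of -6.19. All 7 lists had an adjusted p of 0.126 with an estimated correlation. This contrast called 6249 probe sets, 42.3% of those tested, with 3098 higher and 3151 lower in the embryo, a balance that turned after quantile normalization (3248 higher, 2904 lower), with log2(value + 1) (2804, 2798), with log2(value + 100) (2888, 2813) and without embryo proper replicate 2 (2261, 2196).

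The endosperm differed from the seed coat by higher oil body, photosynthesis and cell cycle transcripts and by lower mucilage and flavonoid transcripts. In the chalazal endosperm the geometric means of 212.5 for oil body, 351.3 for photosynthesis and 106.1 for storage genes lay below those of the general seed coat (2452, 1164 and 752.3) and above those of the chalazal seed coat (88.41, 213.6 and 80.57). For cell cycle, mucilage and flavonoid genes it stood on the same side of both seed coat regions as the other endosperm regions, with 548.6 for cell cycle genes against 132.7 and 133.4. ALPHA-VPE, a vacuolar processing enzyme, was at 7451 ± 1860 in the peripheral endosperm and 134.1 ± 35.4 in the chalazal seed coat, a log2 difference of 3.89 ± 0.27 (SE) between the regions with an adjusted p of 1.2e-08. TET4, a tetraspanin, was at 4303 ± 378 in the micropylar endosperm and 171.6 ± 1.54 in the general seed coat. EEL, a bZIP factor of seed maturation, lay at or above 10420 ± 688 in the 3 endosperm regions and at or below 1725 ± 645 in the 2 seed coat regions. BZIP53, the other maturation regulator tested, was lower in the endosperm (log2 difference -1.08, adjusted p = 0.000184), and the list was not called (adjusted p = 0.571). Lower were TBL38, a trichome birefringence-like gene at 13660 ± 4760 in the chalazal seed coat, with a log2 difference of -6.50, JMT, a jasmonate methyltransferase (-5.81), and ARA12 (-4.58). Cell cycle genes (3 of 3, adjusted p = 0.011) and oil body genes (2 of 2, 0.00692) were higher, and mucilage (4 of 4, 0.000297) and flavonoid genes (2 of 2, 0.00541) lower, each with an adjusted p of 0.126 with an estimated correlation. Photosynthesis genes (3 of 4, 0.00208) and storage genes (3 of 4, 0.0254) were higher, with an adjusted p of 0.172 and 0.246 with an estimated correlation. Limma called 4822 probe sets, 2096 higher and 2726 lower in the endosperm, and after quantile normalization the balance turned, with 2520 higher and 2368 lower.

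Micropylar and peripheral endosperm were the most similar pair of compartments, and the sugar exporters SWEET11 and SAG29 had lower levels in the micropylar region. The geometric mean of 7 SWEET genes, a family chosen later, was 252.5 ± 23.7 in the micropylar and 318.9 ± 83.6 in the peripheral endosperm. SWEET11 and SAG29 were lower in the micropylar endosperm (2 of 2 sugar transport genes, adjusted p = 0.0049, not called with log2(value + 1)), with an adjusted p of 0.137 with an estimated correlation. SWEET11 passed narrowly in limma (log2 difference -1.54, adjusted p = 0.0467). Its own call in this contrast was not followed under the alternatives. AT3G24250 was at 7583 ± 1950 in the micropylar and 73.12 ± 72.2 in the peripheral endosperm, a log2 difference of 6.35 ± 0.56 (SE) with an adjusted p of 8.24e-06, and at 5530 ± 1250 in the embryo proper. DI21 was higher in the micropylar endosperm by 4.39 on the log2 scale. AT5G11230 was at 1052 ± 578 in the micropylar and 8943 ± 2460 in the peripheral endosperm, a log2 difference of -3.13. FaTA, at 2955 ± 302 against 6264 ± 1600, was the 1 of 2 fatty acid synthesis genes that was lower (adjusted p = 0.024, and an adjusted p of 0.126 with an estimated correlation). The cell cycle genes had a median above 0 and a mean below 0 (adjusted p = 0.736). There were 931 called probe sets, 598 higher and 333 lower in the micropylar endosperm. Their number was 162 without micropylar replicate 3, 348 without peripheral replicate 1, 2184 without peripheral replicate 2, 620 without embryo proper replicate 1 and 541 with log2(value + 1). Without micropylar replicate 3 or peripheral replicate 1, SAG29 was no longer called (adjusted p = 0.0852 and 0.0535).

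The chalazal endosperm differed from both other endosperm regions by lower storage, oil body, photosynthesis, sugar transport and flavonoid transcripts and by bright transcripts of its own. SBT4.13, a subtilase, was at 38850 ± 9510 in the chalazal, 110.9 ± 30.1 in the peripheral and 85.43 ± 4.85 in the micropylar endosperm. AT1G19320 was at 27630 ± 5680 against 19.92 ± 9.44 in the peripheral endosperm, a log2 difference of 9.05 ± 0.57 (SE) with an adjusted p of 6.6e-09. BGLU44, a beta-glucosidase, was at 20.6 ± 19.6 in the chalazal and 16960 ± 2940 in the peripheral endosperm (log2 difference -8.38), and SWEET11 differed by -7.68. AT1G50650, listed as KRS, a peptide gene of the endosperm next to the embryo, was at 77.34 ± 86.7 in the chalazal and 15050 ± 1800 in the peripheral endosperm. Against the peripheral endosperm, photosynthesis genes (4 of 4, adjusted p = 0.000297), oil body genes (2 of 2, 0.00104) and sugar transport genes (2 of 2, 0.00132) were lower in the chalazal endosperm, all with an adjusted p of 0.126 with an estimated correlation, as were storage genes (3 of 4, 0.00494, and an adjusted p of 0.161 with an estimated correlation) and flavonoid genes (2 of 2, 0.0357, not called with log2(value + 100), and an adjusted p of 0.14 with an estimated correlation). Against the chalazal endosperm, the micropylar endosperm had higher storage genes (4 of 4, 0.000879) and oil body genes (2 of 2, 0.00187), also with an adjusted p of 0.126 with an estimated correlation, and higher photosynthesis genes (4 of 4, 0.000327, and an adjusted p of 0.13 with an estimated correlation) and sugar transport genes (2 of 2, 0.0129, and an adjusted p of 0.161 with an estimated correlation). Flavonoid genes were higher there too (2 of 2, 0.0446, not called with log2(value + 100), and an adjusted p of 0.154 with an estimated correlation). BGLU29 was higher there by 6.55 on the log2 scale. Chalazal and peripheral endosperm differed at 5159 probe sets, 2655 higher and 2504 lower in the chalazal region. This balance turned after quantile normalization (2425, 2605), with log2(value + 1) (2341, 2371), with the 75th percentile filter (1891, 2086) and without peripheral replicate 1 (2157, 2416), chalazal replicate 1 (2118, 2218) or chalazal replicate 2 (2081, 2128). Micropylar and chalazal endosperm differed at 5387, 2852 higher and 2535 lower in the micropylar region.

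Within the seed coat, oil body, photosynthesis and storage transcripts were lower in the chalazal region, which had a sugar exporter and a transcription factor at high levels. SWEET10 was higher in the chalazal region by 8.19 on the log2 scale, and HAT2, a homeodomain-leucine zipper factor, was at 6424 ± 437 against 33.47 ± 35.5 in the general region. AT3G10590 was at 32000 ± 7960 against 78.09 ± 95.6, a log2 difference of 8.50 ± 0.57 (SE) with an adjusted p of 1.58e-07, and stood at 4017 ± 33.3 in the chalazal endosperm. Lower in the chalazal region were SAG29, at 139.6 ± 84.4 against 4768 ± 1210, OLEO3, at 381.8 ± 338 against 10450 ± 5030, and AT1G12010, with a log2 difference of -6.16. Oil body genes (2 of 2, adjusted p = 0.000297, and an adjusted p of 0.126 with an estimated correlation) and photosynthesis genes (3 of 4, 0.000879, and an adjusted p of 0.159 with an estimated correlation) were lower. Storage genes were lower too, 1 of 4 over all genes tested and 3 of 4 adjusted over the list alone (0.00399, and an adjusted p of 0.161 with an estimated correlation). Mucilage genes, with 1 higher and 1 lower of 4 (3 past the threshold adjusted over the list alone), had a median below 0 and a mean above 0 (adjusted p = 0.57). The LEA genes, 1 of 6 higher, likewise had a median below 0 and a mean above 0 (adjusted p = 0.866). In limma 2425 probe sets differed, 1218 higher and 1207 lower in the chalazal region, and 1559 (762 and 797) without chalazal seed coat replicate 1. With log2(value + 1) there were 883 higher and 909 lower, so neither direction prevailed.

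Whole seed sections were set against the mean of the 6 compartments. Embryo and seed coat transcripts of high level stood above that mean: AT1G04660 was at 109400 ± 2070 in whole seeds and 71110 ± 4710 in the embryo proper, AT1G62070 at 24210 ± 696 and 76690 ± 19900 in the general seed coat, and AT1G62500 at 8561 ± 3990 in whole seeds, a log2 difference of 5.81 ± 0.64 (SE) with an adjusted p of 3.69e-05. AT5G05250 was lower, at 290.1 ± 67.1 against 15550 ± 3300 in the chalazal seed coat, and so was AT4G37180, at 259.1 ± 47.1 against 7034 ± 1100. Limma called 1096 probe sets, 940 higher and 156 lower in whole seeds, which is 85.8% higher. The contrast itself favours such an excess, since whole seeds mix the compartments and are set against a mean of log2 levels. Of the 940, 598 (63.6%) had their highest compartment level in the embryo proper and 132 (14%) in the general seed coat. After quantile normalization 998 were higher and 319 lower, 75.8% higher. The median over all probe sets tested was 0.16 as deposited and 0.01 after quantile normalization. The count was 292 without whole seeds replicate 1 and 285 without whole seeds replicate 2.

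**Figure D4:**
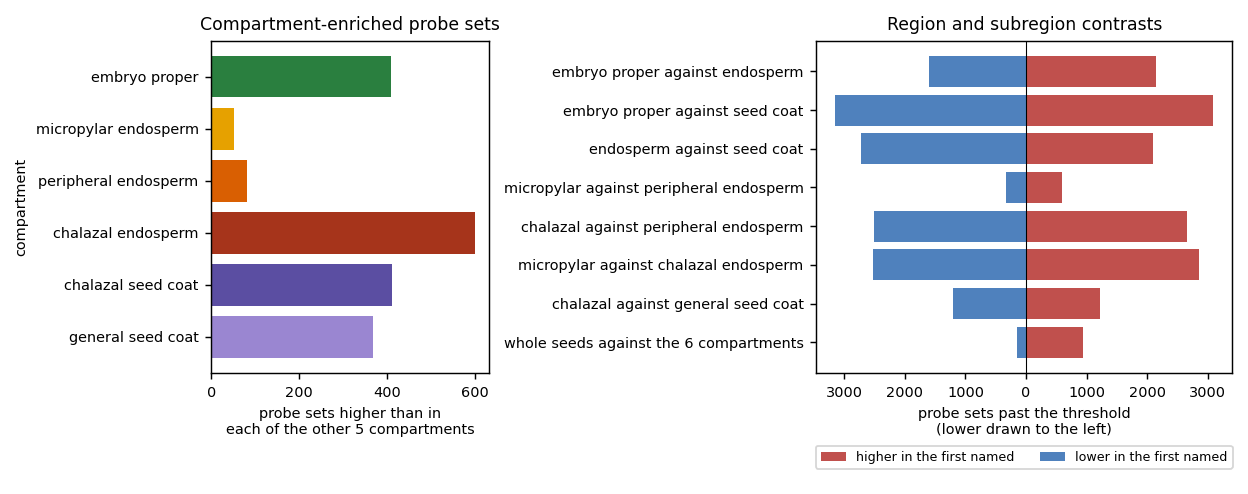
Number of probe sets enriched in each compartment (left, bars from 0) and number higher or lower in the first named group of each contrast (right, lower counts drawn to the left of 0). The chalazal endosperm has 602 enriched probe sets and the micropylar endosperm 51, and 6249 probe sets differ between embryo proper and seed coat.

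Several gene lists had few or no members with a probe set of a single gene. Of 7 measured endosperm regulators and imprinted genes, IKU1 alone passed the brightness filter, at 863.4 ± 85.2 in the chalazal seed coat and 127.2 ± 58.6 in the embryo proper. Its call between embryo proper and seed coat (log2 difference -2.20, adjusted p = 0.00647) ended without embryo proper replicate 2 (0.0962). AGL62, IKU2, MPC, SHB1, AT4G36590 (AGL40) and AT5G26630 (AGL35) stayed below the filter in all 7 groups. FACT of the suberin and cutin list and EXPA8 of the mannanase and expansin list also stayed below it, so neither list has a tested member. No member of the lists for amino acid and mineral transport, phloem, xylem and secondary wall, or gibberellin, abscisic acid and cytokinin metabolism could be named here, and these lists were not analysed here.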

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

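The tests of section purity in this part were chosen after the results they measure had been seen. The chalazal endosperm and the chalazal seed coat lie next to each other, and the difference between chalazal and other tissue was compared between endosperm (chalazal against peripheral) and seed coat (chalazal against general) by a test of the difference itself. The effects differed at 3187 probe sets (21.6% of those tested), and 226 had opposite effects that both passed the threshold, 70 higher in the chalazal endosperm and lower in the chalazal seed coat and 156 the other way round. The genes named in this paragraph and the next were chosen after their values were seen. AT1G47400 had a log2 difference of -4.45 in the endosperm and 5.03 in the seed coat (difference -9.48, adjusted p = 8.35e-06). AT4G18280 had -3.70 and 5.62 (difference -9.32, adjusted p = 1.53e-07), and AT5G66150 had 2.499 and -4.29.

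Many other probe sets moved together at the chalazal pole: 369 were higher in both chalazal tissues, with 219 expected if the calls were independent, and 559 were lower in both, with 205 expected. Higher and lower calls were near equal in number, 2655 and 2504 in the endosperm contrast and 1218 and 1207 in the seed coat contrast. Independent calls would thus give each opposite class a number near 219 and 205, and the 70 and 156 found were fewer. AT3G10590 was higher by 6.75 in the endosperm and 8.50 in the seed coat, SBT4.13 by 8.08 and 4.70, and AT1G19320 by 9.05 and 5.64. AT4G36700 was lower, with -6.03 and -5.86, and OLEO3 with -4.62 and -4.87. Peripheral endosperm tissue in the general seed coat sections, which was not tested, stays open for the calls lower in both.

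Chalazal endosperm transcripts were also present on the chalazal seed coat arrays. The reverse admixture, chalazal seed coat tissue in the chalazal endosperm sections, is argued against by 245 bright chalazal seed coat transcripts, whose level in the chalazal endosperm had a 5th percentile of 0.261% of the seed coat level. Chalazal endosperm tissue in the chalazal seed coat sections stays open: over 373 bright chalazal endosperm transcripts the 5th percentile was 6.89%, with 7.3% and 5.69% on the single arrays, against 0.327% on the general seed coat arrays. The choice of transcripts required lower levels in the general seed coat, so that value is not a free comparison. For 430 bright general seed coat transcripts, chosen without regard to the chalazal seed coat, the 5th percentile on the chalazal seed coat arrays was 6.87%. Transcription in both tissues stays open as well, since 15.8% of the 373 transcripts lay within a factor of 2 of their chalazal endosperm level, and both may hold together.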

How the results depend on the processing

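All alternatives were planned. Over the counts, the named genes and the called fixed lists, 6182 values kept their direction and their side of the threshold (total counts stayed within 1.5 times) and 0 reversed. A further 6, all counts, rose by over 1.5 times. Another 209 fell below the threshold or, for counts, fell by over 1.5 times. The named pairs and called lists were chosen as passing in these data, so they could only stay or fall, and the high share kept partly reflects that choice. The balance of higher and lower calls is not among these values. The fixed lists were run under the settings given below, and the added families under the estimated correlation alone. The purity percentiles were run under none, with some given for single arrays. With n = 2, and with dim probe sets close to background, the counts depend on the offset and on single arrays; the cause was not tested.

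With log2(value + 1), enriched probe sets numbered 205 (embryo proper, 409 as reported), 20 (micropylar, 51), 33 (peripheral, 81) and 363 (chalazal endosperm, 602), 233 (chalazal, 412) and 183 (general seed coat, 369), and micropylar against peripheral endosperm 541 (931). With log2(value + 100) the micropylar count was 111 and the peripheral 124, and without the micropylar arrays the peripheral count was 313, with fewer compartments to pass. Quantile normalization left endosperm against seed coat at 2520 higher and 2368 lower (2096 and 2726 as reported), with the median moving from -0.0447 to 0.0841. The balance also turned for embryo proper against seed coat (3248 higher, 2904 lower) and chalazal against peripheral endosperm (2425, 2605). Of the 66 called list tests, 66 were also called after quantile normalization, 61 with log2(value + 1), 62 with log2(value + 100), 66 with the mean over probe sets and 0 with an estimated correlation in camera (50 at an unadjusted p under 0.05). Of 249 named gene and comparison pairs, 231 passed with log2(value + 1), 248 with no filter and 249 with log2(value + 100).

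With the replicate block, enriched counts were 20 (micropylar) and 12 (peripheral endosperm), micropylar against peripheral 136 and micropylar against chalazal endosperm 3513 (5387 as reported), 64 of the 66 list tests were called and 228 of 249 pairs passed. No other array shares the number of micropylar endosperm replicate 3, so the block gave that array a term of its own. In effect this fit left that array out, and it cannot separate blocking by number from the loss of that array. Deviations of same-numbered arrays correlated between -0.062 and 0.045 over 21 pairs of groups, so the numbers do not pair the arrays.

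Leaving out each array in turn, with the lone array assumed to vary like the other groups, gave these lowest and highest counts. For the enriched counts and contrasts given here the highest came without peripheral replicate 2. Enriched: embryo proper 179 (without embryo proper replicate 1) to 430, micropylar 20 (without micropylar replicate 3) to 86, peripheral 18 (without micropylar replicate 3) to 152, general seed coat 221 (without chalazal seed coat replicate 1 or general seed coat replicate 2) to 406. Contrasts: embryo proper against endosperm 1910 (without embryo proper replicate 2) to 4267, micropylar against peripheral 162 (without micropylar replicate 3) to 2184, chalazal against general seed coat 1559 (without chalazal seed coat replicate 1) to 2857, whole seeds 285 (without whole seeds replicate 2) to 1329. The other counts stayed within 1.5 times, and 231 (without micropylar replicate 3) to 249 (without chalazal endosperm replicate 1 or chalazal seed coat replicate 2) pairs passed.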

Other observations

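The gene families in the next paragraphs, the genes named from them the tests of embryo RNA on the micropylar arrays and the splits of whole compartments were chosen after the global results had been seen. Nuclear genes for chloroplast proteins set the embryo proper and the micropylar and peripheral endosperm apart from both chalazal tissues. They were higher than in the mean of the other compartments in the embryo proper (18 of 21, adjusted p = 1.54e-13), the micropylar endosperm (19 of 21, 2.59e-14) and the peripheral endosperm (17 of 21, 9.16e-12), and lower in the chalazal seed coat (19 of 21, 6.91e-16), each with an adjusted p of 0.119 with an estimated correlation. They were also lower in the chalazal endosperm (18 of 21, 1.14e-09, and 0.138 with an estimated correlation) and the general seed coat (6 of 21, 0.000664, and 0.381 with an estimated correlation). PRK, the phosphoribulokinase of the Calvin cycle, was at 16430 ± 1010 in the embryo and 291 ± 256 in the chalazal seed coat, and PORB, a protochlorophyllide reductase, at 7176 ± 717 in the embryo and 48.71 ± 60.1 in the chalazal endosperm. Plastid-encoded genes for transcription and ribosomes were higher in the embryo (16 of 19, 2.42e-13, and 0.119 with an estimated correlation), with rpoB at 8490 ± 1080 against 2410 ± 244 in the micropylar endosperm, and lower in the chalazal seed coat (15 of 19, 1.87e-10, and 0.135 with an estimated correlation) and the chalazal endosperm (4 of 19, 0.00124, and 0.406 with an estimated correlation). Plastid-encoded photosynthesis genes were lower in the chalazal seed coat (25 of 33, 1.25e-19, and 0.119 with an estimated correlation) and not called in the chalazal endosperm (4 of 33 lower, 0.195), where plastid-encoded NDH genes were not called either (0 of 10 past the threshold in limma, camera adjusted p = 0.678, unadjusted p = 0.52). The geometric mean of the plastid-encoded photosynthesis genes was 8681 ± 162 in the embryo. It was 10460 ± 962 in the micropylar, 10640 ± 1300 in the peripheral and 6071 ± 57.6 in the chalazal endosperm. Mitochondrion-encoded genes were higher in the chalazal seed coat (6 of 15, 4e-05, and 0.236 with an estimated correlation), with cox1 at 28670 ± 2970 there against 5138 ± 314 in the embryo. Their geometric mean was close in the 2 seed coat regions, 4789 ± 26.1 in the chalazal and 4509 ± 88.1 in the general one. In the other compartments it lay between 1867 ± 77.4 (embryo proper) and 2502 ± 41 (chalazal endosperm).

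Cell division genes were higher in the embryo proper (16 of 23, adjusted p = 1.63e-05, and 0.119 with an estimated correlation), with TOPII, a DNA topoisomerase, at 7927 ± 512 against 320.8 ± 58.3 in the chalazal seed coat. The centromeric histone gene HTR12 stood at 978.2 ± 33.6 in the chalazal endosperm and 604.3 ± 88.1 in the embryo. ATG8 genes of autophagy were higher in the chalazal seed coat (6 of 8, 0.000629) and lower in the embryo (4 of 8, 0.000743), each with an adjusted p of 0.119 with an estimated correlation, and ATG8F was at 14250 ± 708 and 2566 ± 68.7. Expansins were higher in the micropylar endosperm (5 of 9 over all genes tested and 7 adjusted over the list alone, 0.00178, and 0.119 with an estimated correlation), with EXPA4 at 4983 ± 1110 against 1315 ± 786 in the peripheral endosperm. Of the GH9 cellulases 4 of 8 were higher and 1 lower in the peripheral endosperm (0.0232, and 0.149 with an estimated correlation), with GH9B8 at 4181 ± 692 against 1525 ± 697 in the micropylar endosperm. SWEET genes were lower in the embryo (4 of 7, 0.0055, and 0.119 with an estimated correlation), and SWEET7 reached 4154 ± 997 in the chalazal endosperm. Vacuolar processing enzymes were lower in the embryo (3 of 4, 0.00178, and 0.177 with an estimated correlation), with DELTA-VPE at 28.09 ± 20.6 against 3523 ± 366 in the general seed coat. Of 286 tests over 22 such families, 79 were called in camera, and 0 with an estimated correlation, where 61 had an unadjusted p under 0.05 and the lowest adjusted p was 0.119.

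Embryo proper transcripts stood on the micropylar endosperm arrays. That these arrays hold embryo proper RNA, as a label field has it, is argued against by 2550 probe sets that differ between these groups, 1208 higher and 1342 lower in the embryo. Embryo tissue in the micropylar sections stays open: over 241 bright embryo transcripts the 5th percentile of the level relative to the embryo was 4.82%, against 1.25% in the peripheral endosperm, which the choice required to be lower. It was 8.12% on micropylar replicate 3 and 1.17% on replicate 1, so such admixture may be a matter of replicate 3. The rise was not particular to embryo transcripts: general seed coat transcripts had 2.05% on replicate 3 and 0.429% on replicate 1. Peripheral endosperm transcripts ran the other way, with 11.3% on replicate 3 and 15.4% on replicate 1. Transcription in both compartments also stays open, with 23.7% of the 241 embryo transcripts within a factor of 2 of the embryo level.

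Whole seeds stood above the mean of the 6 compartments far more often than below it. Many strong transcripts confined to tissue that was not microdissected are argued against by a count of 1 probe set past the threshold above all 6 compartments, 256929_at, at 240.4 in whole seeds and 51.33 in the embryo proper. Weaker ones stay open, since the test can miss them. The simulation held no test of whole seeds against each compartment. In it, compartment enrichment by a log2 difference of 2 was recovered in 24% (peripheral endosperm) to 48% (chalazal endosperm). These shares are not a miss rate for the whole seed test. A mixture of compartments set against a mean of log2 levels favours higher calls by design, for transcripts confined to few compartments. How much of the excess this gives was not tested: 256929_at is 0.106% of the 940 that were higher, and 784 of them (83.4%) lay at or below their highest compartment. The rest of the 940 lay above every compartment, all but 256929_at without passing the threshold against each. Against single compartments whole seeds differed at 1077 probe sets (embryo proper), 1278 (micropylar), 1871 (peripheral) and 5015 (chalazal endosperm), 4091 (chalazal) and 3371 (general seed coat).

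For endosperm against seed coat, other splits of the 10 arrays into 6 and 4 were fitted, 100 drawn of 210. The real split called 2007 probe sets in this fit of 2 groups and the highest other drawn 1191, and 1 split, the real one, reached its count. Most such splits part replicate arrays of a compartment. With both arrays of a compartment kept together there are 10 splits, too few for a share under 0.05, and 2 of them called as many as the real one: the real one and a split not among the 100 drawn, with 2059, which parts the micropylar and peripheral endosperm from the chalazal endosperm and both seed coat regions. The compartments thus group by more than endosperm and seed coat.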
